A study of Mus musculus with 9 samples.

How the data were processed

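Total RNA from the abdominal aorta of uMT mice, 9 samples, was measured on 1-colour Agilent arrays, 1 array per sample. Per the labels, RNA was taken up in TRIzol, amplified and labelled with Cy3 in a low-input kit. The labels name 2 purification kits, SV Total RNA Isolation in the extraction protocol and RNeasy in the design text, and which was used is not settled here. Groups were read from the sample titles, with 3 arrays each for sham, CaCl2, and CaCl2 plus IgG. The day of sampling of the sham mice is not given in the sources used here.

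The deposited scanner files hold spot intensity values on a linear scale. Per the file headers, they were made with Feature Extraction 10.7.1.1, which subtracted the background and removed spatial trends within each array. The submitters' processing notes name Feature Extraction 9.5.1.1. No normalization between arrays is recorded in the scanner files. The authors' deposited series table also holds intensity values, on a linear scale and not centred. All 9 of its columns share a median of 29.7 and an SD of 3.68 in log2 units, and each column followed the processed signal of its own array best, with correlations of at least 0.999 across probes. Its columns were taken as quantile-normalized intensity, but the steps behind them are not given in the sources used here. The series table served as an alternative. In CaCl2 against sham it called 5875 genes, against 5881 with quantile normalization, so among the other scalings it nearly repeats that one. Columns not mapped to a sample numbered 0.

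Processed signals were put on the log2 scale and the 75th percentile of the non-control spots of each array was subtracted. Control spots and outlier spots were left out, saturated spots were kept, and spots of 1 probe were averaged. A probe was kept if it was well above background on all arrays of at least 1 group. Of 55681 probes, 27235 were named through their accession in the reference table of RefSeq genes of mouse assembly GRCm38.p6, 4146 through their symbol there and 1417 only by the name in the files, and 22883 had no gene symbol. A symbol was thus given to 32798 probes. The filter kept 32168 of all probes, among them 9869 without a symbol, which were not part of the gene tests. A gene was represented by the probe with the brightest mean over the 9 arrays, leaving 16411 genes. Of 117 called genes that the naming rule took, 16 had several kept probes, and those of Flt3 and Kdr differed in sign. No genome was used, so no coordinates are given.

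Where no probe of a gene was well above background on any array of a group, its level there is only a bound. The ratio is then given as at least N-fold, from the mean of the brighter group and a floor in the dimmer group. The floor was, per array, the higher of the lowest signal among probes well above background and the signal of the probe itself.

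Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), reading files with the data.table package, version 1.17.8. The 9 arrays entered 1 fit with the 3 groups and no covariate, which left 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. The 27 gene lists, of at least 3 measured members, were tested with camera at its preset correlation of 0.01 and adjusted over the lists of a comparison, 81 tests over the 3 comparisons. Camera with an estimated correlation called 0 lists in each comparison. The self-contained test fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes, called 21, 0 and 21. The groups, tests, gene lists, naming rule and the other settings tried, except where stated, were fixed before the data were examined.

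The lists covered markers of monocytes and macrophages, neutrophils, T and NK cells, B and plasma cells, mast cells, smooth muscle, fibroblasts, endothelium, white and brown fat, skeletal muscle, nerve, mesothelium, adrenal and kidney, and erythroid cells. The others covered collagen and matrix, elastic fibres, matrix proteinases, cytokines, Fc receptors and Syk signalling, complement, interferon-stimulated genes, MHC class II, cell cycle, osteochondrogenic genes, fatty acid oxidation and immediate early genes. Genes were named by a rule. It took the 8 largest increases and decreases among called genes whose arrays did not overlap, and filled up to 5 per direction by smallest p where fewer passed, leaving out Riken and predicted clone names and, as a choice not written in the rule, names without a match in the reference table, such as Igh-VJ558. It added up to 4 called members of each list that passed or had at least 3 called members, and a fixed set that included Mmp9, Mmp2, Syk, the Fc receptor genes, Il6, Ccl2, Acta2, Eln and the B cell genes. Members of lists that moved against the rest, Timp1 in the comparison of CaCl2 with sham, and the list members named in the comparison of CaCl2 plus IgG with CaCl2 were chosen after their values were seen. Some genes that the rule names are not reported here.

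The steps were tested on simulated data with 16411 genes, of which 200 were changed, 50 at each of 4 sizes. For CaCl2 against sham, 0%, 36%, 86% and 98% of genes changed by 0.5, 1, 2 and 4 on the log2 scale were recovered, with 7 false among 117 called. For CaCl2 plus IgG against CaCl2 the shares were 6%, 52%, 76% and 100%, with 9 false among 126 called. For CaCl2 plus IgG against sham they were 0%, 48%, 90% and 98%, with 5 false among 123 called. Genes were simulated as independent, with the same spread in every comparison and no outlying array. Differences between the comparisons thus come from the genes and noise drawn. A list shifted by 1 on the log2 scale was recovered in each comparison, and in CaCl2 plus IgG against CaCl2 1 list that had not been shifted was called as well, against 0 in the other comparisons.

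Precision rests on 3 arrays per group. Between 54.9% and 59.9% of probes were well above background per array. The arrays lay on 2 slides scanned separately, 8 on slide 1 and sham replicate 3 alone on slide 2. A fit with slide as a block is then the fit without that array. On slide 1 the CaCl2 arrays and IgG replicate 1 lay in row 1, and the other sham and IgG arrays in row 2. The alternatives were quantile normalization, normexp background correction with offset 50 and quantile normalization, median scaling, the series table, no filter or a stricter filter on dim probes, and the mean of the probes of a gene. Further ones were another variance model, array weights, only the 2 groups compared, the replicate number as a block, slide row as a block, a fold change of at least 2 in addition, and each array left out in turn. The fits without both sham replicate 3 and IgG replicate 3 were added after seeing the data.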

Results

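Gene expression in the abdominal aorta was measured in 9 samples from B cell-deficient mice of the uMT genotype on the C57BL/6 background. In uMT mice the membrane form of the IgM heavy chain is not made, and B cell development stops early. The samples formed 3 groups of 3 arrays. Sham mice had saline applied around the aorta. CaCl2 mice had 0.5 M CaCl2 applied in the same place, a procedure used to induce abdominal aortic aneurysm. The third group had CaCl2 in the same way and intraperitoneal injections of mouse polyclonal IgG. Aortas of both CaCl2-treated groups were taken on day 7 after CaCl2. The series title names B cells, immunoglobulins and the kinase Syk, and the groups address what CaCl2 changes in the aorta without B cells and whether injected IgG alters those changes. Each sample was hybridised to a 1-colour Agilent mouse array of 55681 probes. Between 54.9% and 59.9% of probes were well above background on each array, and 0 probes were saturated. The 75th percentile of the signal, to which each array was scaled, was 271, 302 and 267 on the sham arrays, 496, 461 and 381 on the CaCl2 arrays, and 449, 455 and 270 on the arrays with IgG. After the filter on dim probes, 16411 genes were tested. The number of arrays, 3 per group, limits the precision of every value. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

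B cell genes were read in every sample as a check of the genotype, on the log2 scale relative to the 75th percentile of each array. Ms4a1, which encodes CD20, read -3.19, -3.11 and -3.02 on the sham arrays, -2.04, -1.82 and 0.16 on the CaCl2 arrays, and -0.65, -1.74 and 0.50 on the arrays with IgG. Cd79a, a part of the B cell receptor, read -2.61, -2.11 and -1.77 in sham aortas, -1.84, -1.81 and 0.16 with CaCl2, and -0.66, -1.25 and 0.11 with CaCl2 plus IgG. Both genes were well above background on 3 of 3 arrays of each group. No probe was named Ighm, the gene altered in uMT mice, so its level was not measured and gives no check of the genotype.

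The first principal component held 69.1% of the variance between arrays and separated sham aortas, at -104 to -78.6, from CaCl2 aortas, at 33.1 to 70.4. Replicates 1 and 2 of the group with IgG lay among the CaCl2 arrays, at 52.8 and 52.2. Replicate 3 of that group stood apart at 2.43, and at -74.4 on the second component, where the other 8 arrays lay between 0.80 and 15.8. Its mean correlation with the other arrays of its group was 0.959 across genes, against 0.979 to 0.990 for the other pairs within groups. Genes are not independent replicates, and these correlations describe the arrays only.

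**Figure D1:**
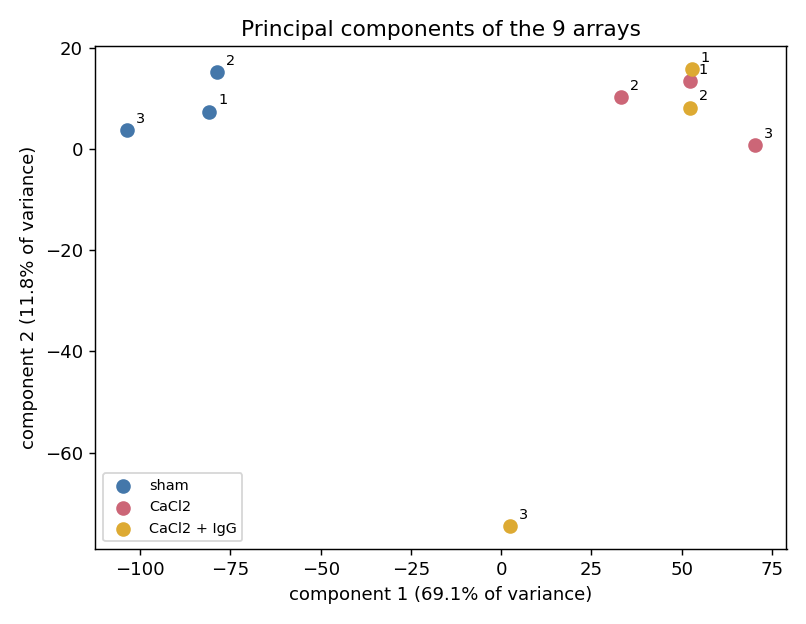
Positions of the 9 arrays on the first principal component (x axis, 69.1% of the variance) and the second (y axis, 11.8%), from log2 values of the tested genes; each point is an array, coloured by group and numbered by replicate. The 3 sham arrays lie at -104 to -78.6 on the x axis, and replicate 3 of the group with IgG lies at -74.4 on the y axis.

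The first comparison asked how aortas treated with CaCl2 differed from sham aortas. Most members of the lists of monocytes and macrophages, T and NK cells, cytokines, matrix proteinases and osteochondrogenic genes were higher with CaCl2. Of 14 contractile genes of smooth muscle 13 were lower. Camera called these lists at its preset correlation, and 0 of 27 lists with an estimated correlation. Spp1, which encodes osteopontin, was higher by 7.35 ± 0.90 on the log2 scale (SE, adjusted p = 0.000964), and Saa3, an acute-phase gene, by 7.55 ± 0.85 (adjusted p = 0.000825), each well above background on 2 of 3 sham arrays. Thbs4, a matrix thrombospondin, was at least 188-fold higher (adjusted p = 0.000154) and Il6, the interleukin-6 gene, at least 42.7-fold higher (adjusted p = 0.00356). Myh11, the smooth muscle myosin heavy chain, fell by 2.37 on the log2 scale (SE 0.32, adjusted p = 0.00145).

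At an adjusted p under 0.05, limma called 6021 of 16411 genes, of which 2869 were higher and 3152 lower with CaCl2. A change of at least 2-fold was seen in 3553 of them, 1924 higher and 1629 lower. The values of the 3 CaCl2 arrays and the 3 sham arrays did not overlap for 9312 genes, 56.8% of those tested, where chance gives 10%. With the median of each array in place of the 75th percentile, the median change of all genes moved from -0.08 to 0.39 on the log2 scale. The share of higher genes among those called then moved from 47.6% to 77.1%, so changes are stated relative to the 75th percentile. With no filter on dim probes 8507 of 23623 genes were called, 2790 higher and 5717 lower, a share of 32.8% higher. Among other genes that the naming rule took as increases by fitted change, Stfa3, Clec4e, Cxcl3 and Mmp13 were at least 200-fold, 28.8-fold, 24.2-fold and 39.6-fold higher. As decreases it took Adam26a, Olfr523, Mybpc2 and Dner, at least 5.95-fold, 3.69-fold, 11.7-fold and 8.51-fold lower, and Vgll2, Col19a1, Slc24a4 and Mylk4, with log2 changes of -3.80, -3.74, -3.71 and -3.66. With CaCl2, Vgll2 was well above background on 2 of 3 arrays, and Col19a1 and Slc24a4 on 1 of 3. The bounds above give no rank among genes, and Adam26a and Olfr523 lost their call with slide row as a block. Another probe of Adam26a was well above background on 0 of 3 arrays in every group, and another of Col19a1 on 1 of 3 sham arrays. Neither was kept, so the values of these genes rest on 1 probe each.

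Most markers of monocytes and macrophages and of T and NK cells rose with CaCl2, as did a minority of neutrophil markers. Of 17 monocyte and macrophage markers measured, 13 rose, 1 fell and 3 did not pass, and 16 passed when adjusted over the list alone (camera adjusted p = 2.93e-06 for the list, and adjusted p = 0.246 with an estimated correlation). The fractalkine receptor gene Cx3cr1 rose by 4.48 ± 0.30 (SE, log2) and the pattern recognition gene Clec7a by 3.60 ± 0.74. Itgam, which encodes the integrin CD11b, was the member that fell, by 1.35 on the log2 scale. Of 11 neutrophil markers, 4 rose and 7 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0220, and adjusted p = 0.246 with an estimated correlation). The calprotectin genes S100a9 and S100a8 rose by 5.43 ± 0.67 and 4.54 ± 0.39, each well above background on 2 of 3 sham arrays. Among 18 T and NK cell markers 14 rose, 1 fell and 3 did not pass, and 15 passed when adjusted over the list alone (camera adjusted p = 3.12e-07, and adjusted p = 0.246 with an estimated correlation). Cd3d and Cd3g, parts of the T cell receptor complex, rose by 4.53 ± 0.51 and 4.17 ± 0.61, each well above background on 2 of 3 sham arrays, whereas Cd4 fell by 0.71. The neutrophil list lost its call where only probes well above background on all 9 arrays were kept (adjusted p = 0.679, with 0.00713 to 0.679 over 22 alternatives).

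In these B cell-deficient mice, some genes of B and plasma cells also rose with CaCl2. Of 12 measured, 5 rose and 7 did not pass, and 8 passed when adjusted over the list alone, 6 higher and 2 lower (camera adjusted p = 0.0161, and adjusted p = 0.280 with an estimated correlation). Jchain, the joining chain of IgA and IgM, rose by 5.55 ± 0.67 (SE, log2, adjusted p = 0.000937). Mzb1, a gene of antibody-secreting cells, was at least 9.14-fold higher (adjusted p = 3.61e-05) and the transcriptional coactivator Pou2af1 at least 10.9-fold. Ms4a1 differed by 1.87 ± 0.67 (adjusted p = 0.0567) and Cd79a by 1.00 ± 0.57 (adjusted p = 0.193), neither past the threshold. Igh-VJ558, an immunoglobulin heavy chain name in the files that is in none of the lists and was chosen after its values were seen, rose by 6.80 ± 1.18 (adjusted p = 0.00387, well above background on 2 of 3 sham arrays). The 3 members with a negative change, chosen after their values were seen, were Pax5 at -1.90 (adjusted p = 0.0509, well above background on 2 of 3 CaCl2 arrays), Cd22 at -1.07 (adjusted p = 0.0957) and Ebf1, a factor of early B cell development, at -0.58 (adjusted p = 0.0758). With only probes well above background on all 9 arrays, the list was no longer called (adjusted p = 0.127, with 0.000267 to 0.127 over 22 alternatives). Mast cell markers fell. Of 7 measured 5 fell and 2 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0162, and adjusted p = 0.402 with an estimated correlation). The mast cell protease genes Mcpt4 and Cpa3 had log2 changes of -2.78 ± 0.53 and -2.29 ± 0.51. This list was not called with the row of the array on its slide as a block (adjusted p = 0.0584, with 0.00113 to 0.0584 over 22 alternatives).

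Most cytokine, Fc receptor and complement genes rose with CaCl2. Of 22 cytokine and chemokine genes 20 rose and 2 did not pass, and 21 passed when adjusted over the list alone (camera adjusted p = 2.31e-10, and adjusted p = 0.246 with an estimated correlation). Il1b, the interleukin-1 beta gene, rose by 6.15 ± 0.57 (SE, log2, well above background on 1 of 3 sham arrays), the monocyte chemoattractant gene Ccl2 by 4.25 ± 0.61, and the neutrophil chemokine gene Cxcl5 was at least 18.5-fold higher. Of 20 Fc receptor and Syk signalling genes 18 rose and 2 did not pass, and 19 passed when adjusted over the list alone (camera adjusted p = 5.68e-10, and adjusted p = 0.246 with an estimated correlation). Syk itself rose by 1.64 ± 0.27 (adjusted p = 0.00330). The receptor genes Fcgr1, Fcgr2b, Fcgr3 and Fcgr4 rose by 2.65, 2.66, 2.39 and 2.71 on the log2 scale, and Fcer1g, the signalling chain of activating Fc receptors, by 2.20. Of 17 complement genes 12 rose, 1 fell and 4 did not pass, and 14 passed when adjusted over the list alone (camera adjusted p = 4.20e-06, and adjusted p = 0.246 with an estimated correlation). C3, the central component, rose by 2.27 ± 0.23 and C1qa by 2.67 ± 0.62, whereas Cd59a, which restrains the membrane attack complex, fell by 0.80.

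Interferon-stimulated, antigen presentation and cell cycle genes were higher with CaCl2. Among 21 interferon-stimulated genes 14 rose and 7 did not pass, and 17 passed when adjusted over the list alone (camera adjusted p = 7.44e-06, and adjusted p = 0.320 with an estimated correlation). Bst2 and Isg15 rose by 4.23 ± 0.58 and 3.83 ± 0.80 (SE, log2). Of 13 MHC class II and antigen presentation genes 11 rose, 1 fell and 1 did not pass, and 12 passed when adjusted over the list alone (camera adjusted p = 1.43e-05, and adjusted p = 0.246 with an estimated correlation). Itgax, the gene of the dendritic cell integrin CD11c, rose by 3.49 ± 0.51 and the migration receptor gene Ccr7 by 3.43 ± 0.31. Flt3 rose by 2.69 ± 0.42 on its brightest probe, and its probes differed in sign. Ciita, the transactivator of MHC class II genes, was the member that fell, by 2.47 on the log2 scale. Of 19 cell cycle genes 13 rose and 6 did not pass, and 15 passed when adjusted over the list alone (camera adjusted p = 6.19e-06, and adjusted p = 0.320 with an estimated correlation). The cyclin gene Ccna2 rose by 2.38 ± 0.38 and the kinase gene Cdk1 was at least 3.38-fold higher. Of 14 immediate early and stress genes 5 rose, 1 fell and 8 did not pass, and 6 passed when adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.532 with an estimated correlation). Fos rose by 4.20 ± 1.21, whereas the heat shock gene Hspa1a fell by 2.22.

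Smooth muscle contractile genes fell nearly throughout. Of 14 measured 13 fell and 1 did not pass, also when adjusted over the list alone (camera adjusted p = 2.61e-07, and adjusted p = 0.280 with an estimated correlation). Acta2, smooth muscle actin, had a log2 change of -1.49 ± 0.23 (SE, adjusted p = 0.00231), Des, the intermediate filament desmin, one of -2.40 ± 0.34, and Myocd, the transcriptional coactivator of contractile genes, one of -2.82 ± 0.48. The fibroblast and adventitial markers moved the other way, with 5 of 12 risen and 7 not past the test, also when adjusted over the list alone (camera adjusted p = 0.00301, and adjusted p = 0.320 with an estimated correlation). Dpt, the matrix protein dermatopontin, rose by 4.91 ± 0.98 and the proteoglycan gene Lum by 1.79 ± 0.16. Endothelial markers were not called as a list (camera adjusted p = 0.872), with 3 of 12 risen, 2 fallen and 7 not past the test, and 5 passed when adjusted over the list alone. Their median change was -0.05, although the test pointed to higher, and it was 0.42 with median scaling. The tight junction gene Cldn5 rose by 2.28 ± 0.36. Vwf, von Willebrand factor, fell by 0.80 on its brightest probe, but its other kept probe had a change of only -0.05. Kdr, the VEGF receptor gene, had a log2 change of -0.83 ± 0.24 (adjusted p = 0.0272) on its brightest probe, but its probes differed in sign and their mean was 0.22 (adjusted p = 0.299).

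Most genes of matrix-degrading enzymes and their inhibitors rose. Of 21 matrix proteinase and inhibitor genes 15 rose, 1 fell and 5 did not pass, and 17 passed when adjusted over the list alone (camera adjusted p = 5.34e-07, and adjusted p = 0.246 with an estimated correlation). Mmp2, gelatinase A, rose by 2.07 ± 0.24 (SE, log2, adjusted p = 0.000848), and the macrophage elastase gene Mmp12 by 3.07 ± 0.67. Mmp9, gelatinase B, differed by 1.63 ± 0.76 and did not pass (adjusted p = 0.123). Its sham arrays read -3.12, -2.04 and -5.63 and its CaCl2 arrays -2.22, -1.80 and -1.90, and 2 of 3 sham arrays were well above background. Timp1, an inhibitor of these enzymes, rose by 2.98. Of 16 fibrillar collagen and matrix genes 8 rose, 1 fell and 7 did not pass, and 9 passed when adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.377 with an estimated correlation). Fap, a protease of activated fibroblasts, rose by 2.52 ± 0.21, whereas Col1a1 differed by 0.76 ± 0.30 (adjusted p = 0.0754). With the row of the array on its slide as a block, this list was not called (adjusted p = 0.0584, with 0.000471 to 0.0584 over 22 alternatives). Elastic fibre genes were not called as a list (camera adjusted p = 0.213), with 2 of 14 risen, 2 fallen and 10 not past the test, and 4 passed when adjusted over the list alone. Ltbp2, a latent TGF-beta binding protein gene, rose by 3.92 ± 0.17, Ltbp1 fell by 1.37, and Eln, which encodes elastin, had a log2 change of -0.45 ± 0.35 (adjusted p = 0.343).

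Genes of cartilage and bone formation rose. Of 17 osteochondrogenic and calcification genes 11 rose and 6 did not pass, and 13 passed when adjusted over the list alone (camera adjusted p = 3.17e-06, and adjusted p = 0.246 with an estimated correlation). The cartilage collagen genes Col2a1 and Col11a1 were at least 26.6-fold and 11.3-fold higher, and Ibsp, bone sialoprotein, rose by 4.73 ± 0.52 (SE, log2). Brown adipocyte and fatty acid oxidation genes were lower as lists. Of 10 brown adipocyte markers 3 fell, 1 rose and 6 did not pass, and 7 passed when adjusted over the list alone (camera adjusted p = 0.0378, and adjusted p = 0.246 with an estimated correlation). Cidea, a lipid droplet gene, had a log2 change of -2.07 ± 0.32, whereas the thyroid hormone deiodinase gene Dio2 rose by 1.87 ± 0.39. This list was not called under 4 alternatives, which were the fits without sham replicate 1, with slide row as a block, with no filter on dim probes and with the stricter filter (adjusted p from 0.00221 to 0.0896 over 22 alternatives). Of 17 fatty acid oxidation genes 5 fell and 12 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.320 with an estimated correlation). Ppara, a regulator of this pathway, had a log2 change of -0.74 ± 0.19, and Acadm, a dehydrogenase of medium-chain fatty acids, one of -0.64 ± 0.14. The median of the fatty acid oxidation list, -0.33, turned to 0.14 with median scaling, and its call was lost there and without the filter on dim probes (adjusted p from 0.00191 to 0.245 over 22 alternatives). White adipocyte markers were not called (camera adjusted p = 0.136), with 3 of 11 fallen, 1 risen and 7 not past the test, and 4 passed when adjusted over the list alone. The glucose transporter gene Slc2a4 fell by 1.36 and Pparg, a regulator of adipocyte formation, rose by 0.83.

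**Figure D2:**
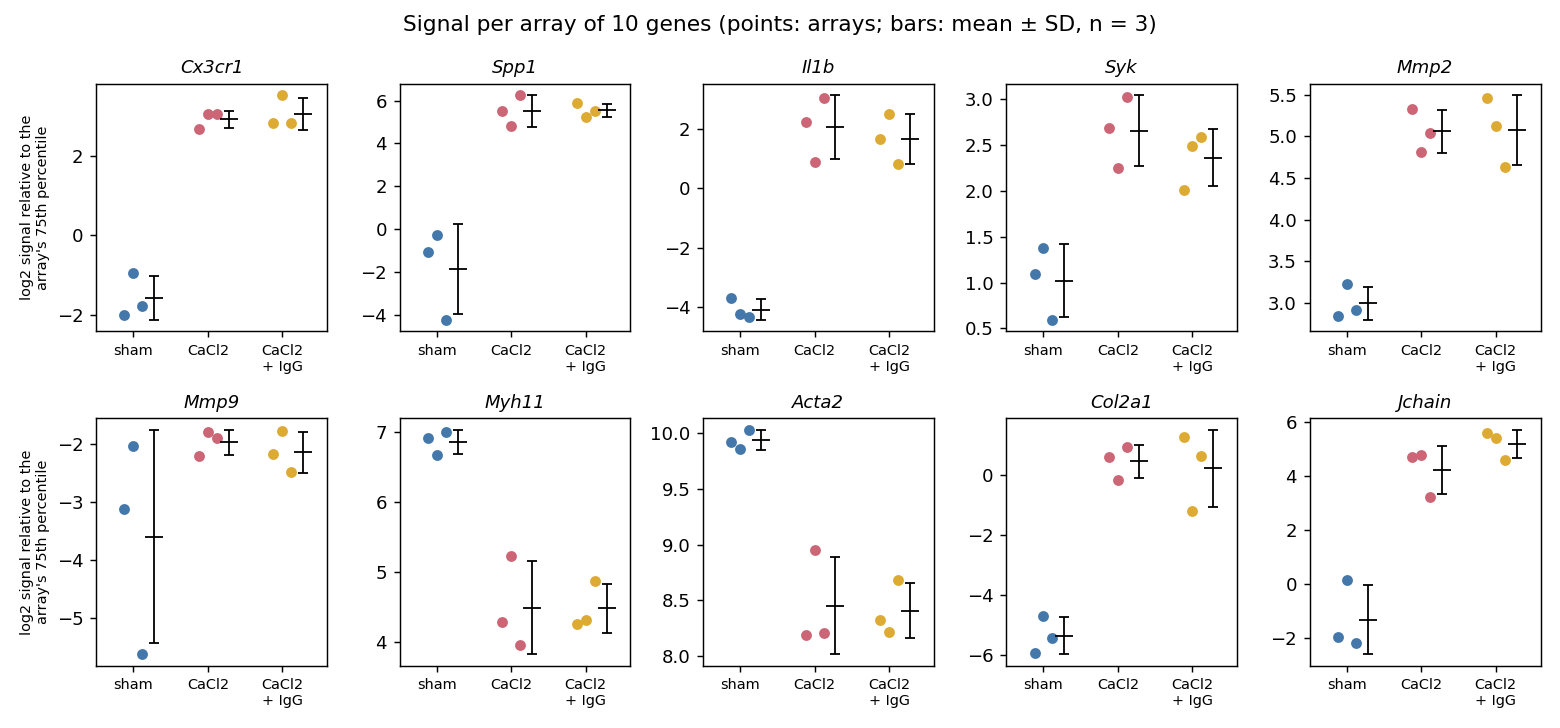
Signal of 10 genes on each array (y axis, log2 relative to the 75th percentile of the array) in sham, CaCl2 and CaCl2 plus IgG aortas; points are arrays and bars the mean and SD of 3 arrays. Cx3cr1, Spp1, Il1b, Syk, Mmp2, Col2a1 and Jchain are higher and Myh11 and Acta2 lower in both CaCl2-treated groups than in sham aortas, while the arrays of Mmp9 overlap.

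In all, 19 of 27 lists were called by camera in CaCl2 against sham, 15 higher and 4 lower, and with an estimated correlation 0 were called. Sham replicate 3 was alone on its slide and scan, and within the other slide, which is the fit without it, 3909 genes were called. On that slide all CaCl2 arrays lay in row 1 and the remaining sham arrays in row 2, so row and treatment cannot be told apart there. Without CaCl2 replicate 1 the count was 3980, and with the row of the array on its slide as a block it was 3382. The fit with rows as a block separates row from treatment only through sham replicate 3, from the other slide, and the arrays with IgG.

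The second comparison asked whether injected IgG changed the aortas treated with CaCl2. No gene passed the test between the 2 groups, among them Syk and the genes of Fc receptors and matrix proteinases. Syk differed by -0.29 on the log2 scale (95% interval -0.92 to 0.33), Mmp2 by 0.02 (-0.52 to 0.55) and Fcgr1 by -0.17 (-1.03 to 0.70). For Mmp9 the difference was -0.17 and the interval was wide, from -1.91 to 1.57. Il6 differed by -0.65 (-3.39 to 2.10), Ccl2 by -0.91 (-2.30 to 0.48), and the contractile gene Myh11 by -0.01 (-0.74 to 0.73). These intervals do not show that the groups were alike.

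At an adjusted p under 0.05, limma called 0 of 16411 genes, and 247 had an unadjusted p under 0.05. The smallest adjusted p was 1.00. Every other scaling, filter and model run with all arrays of both groups also called 0, with 173 to 757 genes at an unadjusted p under 0.05. The smallest adjusted p among these fits was 0.0743, with array weights. Without replicate 1 of the group with IgG, 2 genes were called, 1700029F12Rik and Olfr701, higher by 2.36 and 2.30 on the log2 scale (adjusted p = 0.0292), which were named after their values were seen. With CaCl2 alone the first was well above background on 1 of 3 arrays and the second on 2 of 3. The arrays of the groups did not overlap for 829 genes, 5.05% of those tested, where chance gives 10%. On simulated data for this comparison, with 16411 genes, 52% of genes changed 2-fold and 76% of those changed 4-fold were recovered. The simulation held independent genes and no outlying array, so these shares need not hold for the real arrays. The genes with the smallest unadjusted p, none past the test, were Myoz1, Rab3b and Spin2c on the higher side, with differences of 0.89, 0.75 and 0.85. On the lower side Wfs1 and Mlana had differences of -0.81 and -0.73. Agr2 was at least 1.55-fold higher, well above background on 1 of 3 arrays with IgG, while Chrna7 and Frem1 were at least 1.41-fold and 1.21-fold lower. Vmn2r82 was not well above background in either group, and Cplane2 was not well above background with IgG, with no fold for either. For Col1a1 and Eln the differences were 0.18 and -0.13, for Acta2 -0.04 and for Il1b -0.39.

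As lists, 5 of 27 passed camera although 0 of their members passed the gene test, and none passed with an estimated correlation or by fry. The members named here were chosen after their values were seen. Interferon-stimulated genes were lower with IgG. Of 21 measured 20 had a negative difference, with a median of -0.55, and 0 passed when adjusted over the list alone (camera adjusted p = 0.000232, and adjusted p = 0.917 with an estimated correlation). Cxcl10, an interferon-induced chemokine gene, differed by -1.82 and Isg15 by -1.02. B and plasma cell markers were higher, with 12 of 12 differences positive, a median of 0.56 and 1 passed when adjusted over the list alone (camera adjusted p = 0.00117, and adjusted p = 0.917 with an estimated correlation). Jchain differed by 0.96 and Mzb1 by 0.76. White adipocyte markers were lower in 11 of 11 cases, with a median of -0.77 and 0 passed when adjusted over the list alone (camera adjusted p = 0.0199, and adjusted p = 0.917 with an estimated correlation). Plin1 and Cidec, which coat lipid droplets, differed by -1.16 and -1.12. Immediate early and stress genes were lower in 14 of 14 cases, with a median of -0.40 (camera adjusted p = 0.0252), and the 4 erythroid genes were higher in 4 of 4, with a median of 1.24 (camera adjusted p = 0.0423). For both lists the adjusted p was 0.917 with an estimated correlation, and 0 members passed when adjusted over the list alone.

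Replicate 3 of the group with IgG lay apart from the other 5 CaCl2-treated arrays in several of these lists. On it the immediate early and stress genes were lower by a median difference of -2.08, in 14 of 14 genes. The interferon-stimulated genes were lower by a median difference of -0.85 in 20 of 21 genes, and the B and plasma cell markers were higher by 1.19 in 10 of 12. White adipocyte markers had a median difference of -0.80 there, in 10 of 11 genes, and cytokine and chemokine genes one of -1.04, with 15 of 22 genes lower. Without this array the calls of B and plasma cell markers (adjusted p = 0.124), white adipocyte markers (adjusted p = 0.114) and immediate early genes (adjusted p = 0.229, direction turned to higher) were lost. All of these were also lost with array weights, the first without CaCl2 replicate 1, the second without CaCl2 replicate 2 or IgG replicate 1, and the third without CaCl2 replicate 1 or 3, with slide row as a block, and under 3 of the 4 other scalings. Their adjusted p ran from 1.68e-07 to 0.207, from 3.04e-05 to 0.982 and from 2.60e-05 to 0.475 over 22 alternatives. Interferon-stimulated genes were still called lower without it (adjusted p = 0.0173), and lost their call without CaCl2 replicate 3, without IgG replicate 1 and with array weights (8.25e-08 to 0.942 over 22 alternatives). The erythroid call was lost under the same 3 and without CaCl2 replicate 2 (1.39e-10 to 0.917). Endothelial markers were called higher (adjusted p = 0.0173, with 0.0173 to 0.937 over 22 alternatives) and brown adipocyte markers lower (adjusted p = 0.0367, with 0.0327 to 0.995) without IgG replicate 3. The number of lists called was 13 with the row of the array on its slide as a block, 1 with array weights, 3 in the fit without CaCl2 replicate 1, and 2 in the fit without IgG replicate 1.

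None of the other 22 lists passed camera between the CaCl2-treated groups. For Fc receptor and Syk signalling genes the median difference was -0.06 (camera adjusted p = 0.593), for matrix proteinases and inhibitors -0.13 (0.479), and for monocyte and macrophage markers 0.05 (0.651), which turned to -0.18 with median scaling. Median scaling moved the median difference of all genes from -0.02 to -0.25. For smooth muscle contractile genes the median difference was 0.02 (camera adjusted p = 0.869), while the test pointed to lower, and the median was negative under 4 other scalings, at -0.05 to -0.22.

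**Figure D3:**
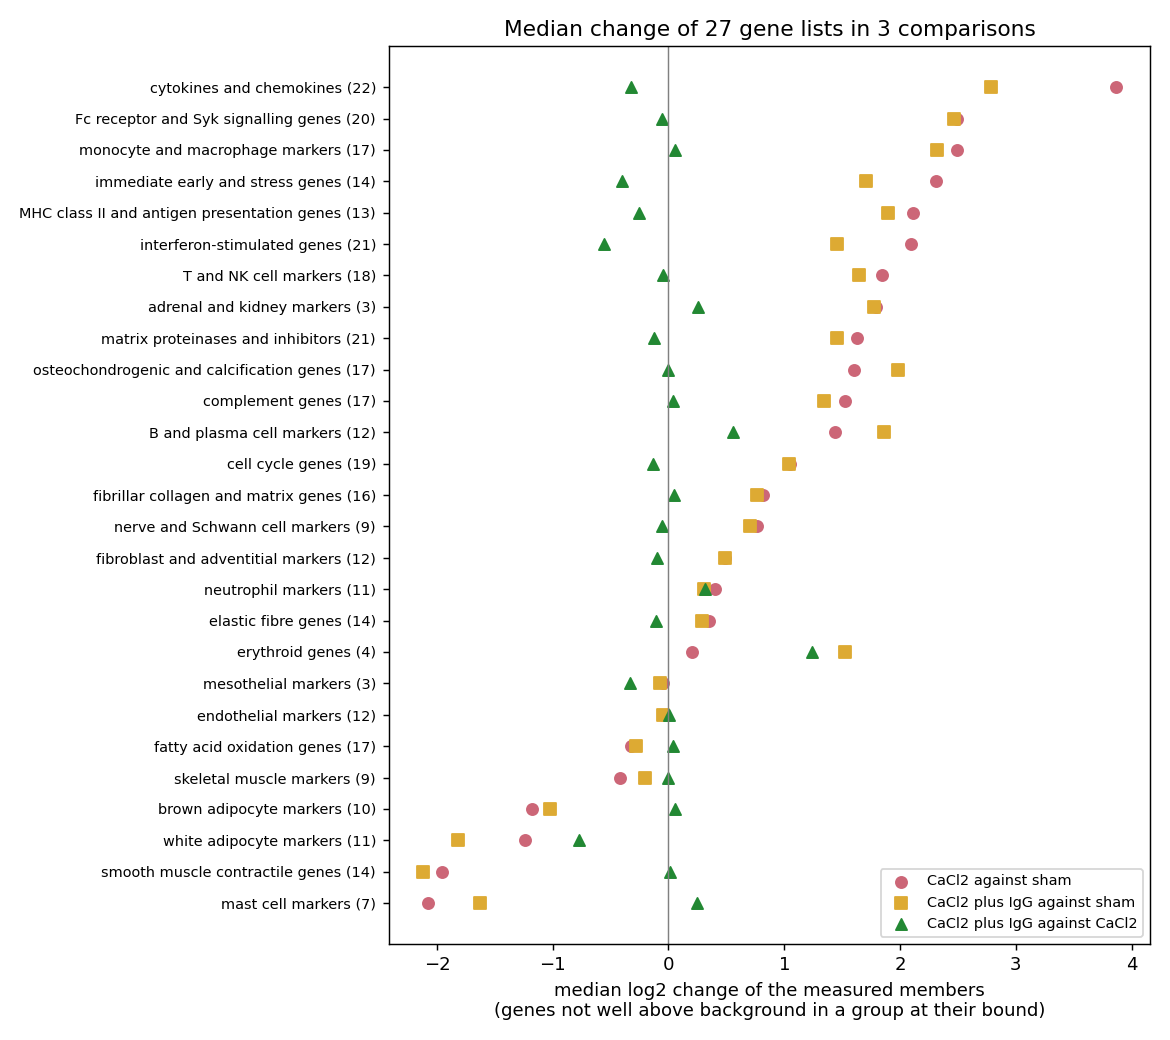
Median log2 change (x axis) of the measured members of 27 gene lists (y axis, members in parentheses) in the 3 comparisons, with genes not well above background in a group set at their bound. The medians of the comparison with and without IgG lie closer to 0 than both comparisons with sham except for neutrophil, mesothelial and erythroid genes, the last at 1.24 against 0.21 for CaCl2 against sham; with median scaling the fatty acid oxidation list turns from -0.33 to 0.14 in CaCl2 against sham, and the endothelial, mesothelial and skeletal muscle lists turn sign there too.

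The third comparison set aortas with CaCl2 and IgG against sham aortas. Most members of the lists of monocytes and macrophages, T and NK cells, cytokines, matrix proteinases and osteochondrogenic genes were higher. Of 14 contractile genes of smooth muscle 13 were lower. Camera called these lists at its preset correlation, and 0 of 27 lists with an estimated correlation. Spp1 was higher by 7.38 ± 0.90 on the log2 scale (SE, adjusted p = 0.00106), Saa3 by 8.19 ± 0.85 (adjusted p = 0.000692) and Jchain by 6.51 ± 0.67 (adjusted p = 0.000690), Spp1 and Saa3 well above background on 2 of 3 sham arrays. Myh11 had a log2 change of -2.38 ± 0.32 (adjusted p = 0.00155). Thbs4, Stfa3 and Il6 were at least 98.0-fold, 192-fold and 27.2-fold higher.

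Here limma called 4767 of 16411 genes, 2430 higher and 2337 lower, and 2652 of them changed at least 2-fold, 1658 higher and 994 lower. The arrays of the groups did not overlap for 7284 genes, 44.4% of those tested, where chance gives 10%. Median scaling moved the median of all genes from -0.09 to 0.14 and the share of higher genes from 51.0% to 71.8%, and called 2979 genes. The complement factor I gene Cfi was at least 22.2-fold higher. Dner, Col19a1, Mybpc2 and Lsamp were at least 6.64-fold, 4.50-fold, 9.12-fold and 7.34-fold lower. For Col19a1 and Lsamp another probe, not kept, was well above background on only 1 of 3 sham arrays. Hhip, an inhibitor of hedgehog signalling, had a log2 change of -3.85 ± 0.49, and Arhgef33 and Xkr4 had changes of -4.04 and -3.46, both well above background on 1 of 3 arrays with IgG.

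Several lists were called higher in this comparison too. Of 17 monocyte and macrophage markers 14 rose (14 adjusted over the list alone), of 20 Fc receptor and Syk signalling genes 18 (18), of 22 cytokine and chemokine genes 17 (20), and of 21 matrix proteinase and inhibitor genes 16, with 1 fallen (17). Their camera adjusted p-values were 1.32e-07, 1.41e-10, 1.41e-10 and 1.50e-07, and the adjusted p was 0.187 with an estimated correlation for each of these 4. Syk rose by 1.34 ± 0.27 (SE, log2, adjusted p = 0.00841), Fcgr4 by 2.69 ± 0.55, Ccl2 by 3.34 ± 0.61 and Mmp2 by 2.08 ± 0.24, whereas Mmp9 differed by 1.45 ± 0.76 (adjusted p = 0.180). T and NK cell markers rose in 14 of 18 cases (16 adjusted over the list alone), complement genes in 13 of 17 with 1 fallen (16), B and plasma cell markers in 6 of 12 (7, with 9 of 12 changes positive), neutrophil markers in 6 of 11 (7) and osteochondrogenic genes in 12 of 17 (12). For these 5 lists the camera adjusted p was 9.91e-08, 3.56e-07, 0.00135, 0.00446 and 1.16e-07, and the adjusted p was again 0.187 with an estimated correlation. Ms4a1 rose by 2.47 ± 0.67 (adjusted p = 0.0256), while Cd79a differed by 1.56 ± 0.57 (adjusted p = 0.0717). The neutrophil list was not called with probes well above background on all 9 arrays (adjusted p = 0.935, with 0.000535 to 0.935 over 22 alternatives).

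Of 21 interferon-stimulated genes 6 rose and 15 did not pass (7 adjusted over the list alone; camera adjusted p = 0.000334, and adjusted p = 0.406 with an estimated correlation), among them Bst2 by 3.42 ± 0.58 (SE, log2). MHC class II and antigen presentation genes rose in 10 of 13 cases (12 adjusted over the list alone; camera adjusted p = 1.16e-05, and adjusted p = 0.212 with an estimated correlation), and cell cycle genes in 12 of 19 (14 adjusted over the list alone; camera adjusted p = 5.83e-06, and adjusted p = 0.296 with an estimated correlation). Of 16 fibrillar collagen and matrix genes 8 rose and 2 fell (10 adjusted over the list alone; camera adjusted p = 0.00931, and adjusted p = 0.374 with an estimated correlation), with Col1a1 risen by 0.95 ± 0.30 (adjusted p = 0.0452). Fibroblast and adventitial markers rose in 4 of 12 cases (5 adjusted over the list alone; camera adjusted p = 0.00370, and adjusted p = 0.336 with an estimated correlation). Immediate early and stress genes rose in 4 of 14 cases and fell in 2 (6 adjusted over the list alone; camera adjusted p = 0.0401, and adjusted p = 0.622 with an estimated correlation). That list lost its call without sham replicate 2 or 3, without IgG replicate 1 or 2, and under each of the 4 other scalings (0.00178 to 0.161 over 22 alternatives). Eln did not pass, with a change of -0.58 ± 0.35 (adjusted p = 0.239).

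Smooth muscle contractile genes fell in 13 of 14 cases (13 adjusted over the list alone; camera adjusted p = 6.61e-08, and adjusted p = 0.215 with an estimated correlation), with Acta2 at -1.53 ± 0.23 (SE, log2). White adipocyte markers fell in 7 of 11 cases (10 adjusted over the list alone; camera adjusted p = 0.0177, and adjusted p = 0.425 with an estimated correlation). Plin1 and the adipokine gene Adipoq had changes of -2.80 ± 0.76 and -2.52 ± 0.77. Brown adipocyte markers fell in 4 of 10 cases and rose in 1 (5 adjusted over the list alone; camera adjusted p = 0.0211, and adjusted p = 0.187 with an estimated correlation). Mast cell markers fell in 3 of 7 (3 adjusted over the list alone; camera adjusted p = 0.0177, and adjusted p = 0.413 with an estimated correlation). Fatty acid oxidation genes fell in 4 of 17 (1 adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.296 with an estimated correlation). Without replicate 3 of the group with IgG, the calls of the white adipocyte, mast cell and fatty acid oxidation lists were lost. Those of white adipocytes and mast cells were also lost without sham replicate 1 and with array weights, and that of fatty acid oxidation with median scaling. The 3 lists had largest adjusted p-values of 0.0889, 0.0902 and 0.125 over 22 alternatives and smallest of 0.000792, 0.000934 and 0.00908. The brown adipocyte list lost its call with probes well above background on all 9 arrays (0.000880 to 0.0557). In all, 20 lists were called, 15 higher and 5 lower, and 0 with an estimated correlation. Without replicate 2 of the group with IgG 3015 genes were called, and with array weights 8434.

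Of the genes called in the comparisons of both CaCl2-treated groups with sham, 2281 were higher in both and 2026 lower in both, where independent lists of these lengths would share 425 and 449. In opposite directions, 0 genes were shared. In 100 simulations with no effect and the same sham arrays, 0.01 genes were shared on average and at most 1. With no effect almost no gene is called, so this count cannot show how much the shared sham arrays add to the real overlap. The log2 changes correlated at 0.96 across genes, against 0.50 in the simulations. Their covariance was 1.04 against 0.0469, a difference of 0.996. The sham arrays, 3 in number, could not be split with at least 2 on each side, and part of the excess may come from these shared arrays. Median scaling gave 2755 shared genes, the fit without replicate 2 of the group with IgG 2838, and array weights 7179.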

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

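The tests on replicate 3 of the group with IgG, the shares of lower calls set against named genes, and the correlation of B cell with plasma cell genes were chosen only after the result was seen. The other tests were set before it.

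Some probes without a gene symbol, which were not part of the gene tests, differed between CaCl2-treated and sham arrays. Of 9869 such probes, 2385 passed limma in CaCl2 against sham, 543 higher and 1842 lower, and 749 passed in CaCl2 plus IgG against sham, 341 higher and 408 lower. Of 16411 named genes, each represented by 1 probe, 6021 and 4767 passed in these comparisons. Scaling was not decided, because another scaling moved the share for named genes too: lower calls made up 77.2% against 52.4% for named genes, 59.5% against 43.4% with quantile normalization, 63.6% against 44.8% with normexp and 48.4% against 22.9% with median scaling. Named probes of the same brightness also lay lower, with bin medians averaging -0.22 against a median of -0.47 for probes without a symbol. The difference averaged -0.33 over 20 brightness bins (log2, SE over bins 0.0614), at -1.41 in the dimmest bin and -0.03 in the brightest. This goes against dimness as the whole cause but does not exclude it, since the named probes include genes that CaCl2 raised. In the dimmest bin the named probes had a median of 0.36 against -1.05. Which transcripts the probes without a symbol measure was not analysed here, and an effect of CaCl2 on them stays open.

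Replicate 3 of the group with IgG lay apart from the other CaCl2-treated arrays. Its 75th percentile was low, at 270, and the handling of low signal stays open, since with normexp its mean correlation with the other arrays of its group was 0.975 against 0.984 for the lowest other pair within a group, a gap of 0.00830 in place of 0.0198. On the values of this array alone, a response to CaCl2 weaker by the same share in every list is argued against. One weaker in part of the lists stays open. The SEs below are over the genes of a list, which are not independent replicates, and they give no spread between samples. Monocyte and macrophage markers of replicate 3 lay 0.0167 of the way from the other CaCl2-treated arrays to sham (SE 0.0723). Its immediate early and stress genes lay 1.09 of the way (SE 0.124, a gap of 1.07, SE 0.143). The share was 0.525 (SE 0.111) for interferon-stimulated genes, 0.761 (SE 0.287) for fibroblast markers and 0.443 (SE 0.180) for collagen and matrix genes. For cytokines it was 0.289 (SE 0.0940), and for Fc receptor and Syk genes 0.0290 (SE 0.0324). Lymphoid tissue in the sample was neither supported nor excluded by T and NK cell markers, with a median difference of 0.21 and a mean of 0.19 (SE 0.0906), but a median of 0.06 and a mean of 0.02 (SE 0.143) with quantile normalization, and a different response of this sample to IgG was not tested.

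In mice meant to lack B cells, 5 of 12 genes of B and plasma cells rose with CaCl2, and 3 others had negative changes that did not pass. Scaling is argued against, since 6 members were higher with quantile normalization and 5 with the 75th percentile, and so is a single mislabelled array, since at least 5 members were higher whichever array was left out. Lymphoid tissue taken with the aorta cannot be told apart from cells within the wall. Over the 6 CaCl2-treated arrays the mature B cell genes Ms4a1, Cd79a and Cr2 and the plasma cell genes Jchain and Mzb1 had r = -0.442 (exact permutation p = 0.388, two-sided) and rho = 0.0857 (exact permutation p = 0.919), and without the 2 arrays farthest from the median r was 0.776, but the 4 arrays left are 2 of each group, with plasma cell means of 1.89 and 1.89 with CaCl2 against 2.67 and 2.64 with IgG, so this value holds the difference between groups. Within each group the array with the highest mature B cell mean had the lowest plasma cell mean, which with 3 arrays decides nothing, 8 of the 12 genes measured were well above background on all sham arrays, and a biological source such as residual B-lineage cells in uMT mice was not tested.

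Chance was examined with the 10 splits of the 6 arrays of each comparison, which are too few for a share under 0.05. The real split gave 6021 genes in CaCl2 against sham and the highest other 0 (1 of 10 splits as large). In CaCl2 plus IgG against sham the real split gave 4767 and the highest other 0 (1 of 10). With and without IgG it gave 0 and the highest other 0 (10 of 10), while at an unadjusted p under 0.05 it gave 247 and the other splits 292 to 1292. Lists numbered 19 against 17 for the highest other split in CaCl2 against sham (1 of 10), 20 against 16 in CaCl2 plus IgG against sham (1 of 10) and 5 against 11 in CaCl2 plus IgG against CaCl2 (9 of 10). In that comparison the 9 other splits called 0 to 11 lists.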

How the results depend on the processing

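The fits that left out both sham replicate 3 and IgG replicate 3 were chosen only after the result was seen. They called 6138 genes in CaCl2 against sham, 0 in CaCl2 plus IgG against CaCl2 and 5415 in CaCl2 plus IgG against sham, with 4956 shared calls and 19, 5 and 19 lists. With the other settings, the count of genes in CaCl2 against sham fell to 3382 with slide row as a block and to 3553 with a fold change of at least 2 in addition, and ranged from 3909 to 7401 with each array left out. In CaCl2 plus IgG against CaCl2 it ranged from 0 to 2 with each array left out, and was 0 otherwise. In CaCl2 plus IgG against sham it was 2979 with median scaling, 8434 with array weights, 2652 with a fold change of at least 2 in addition, and 3015 to 6663 with each array left out. Shared calls were 2755 with median scaling, 7179 with array weights and 2838 to 6113 with each array left out. Lists called in CaCl2 against sham numbered 0 with an estimated correlation and 18 to 20 with each array left out. Between CaCl2 plus IgG and CaCl2 they numbered 1 with array weights, 13 with slide row as a block, 0 with an estimated correlation, 0 by fry and 2 to 6 with each array left out. Against sham, CaCl2 plus IgG gave 0 lists with an estimated correlation and 17 to 21 with each array left out. Kdr changed direction with the mean of its probes, to 0.22 in CaCl2 against sham and 0.15 in CaCl2 plus IgG against sham, since its probes differ in sign. Leaving out an array leaves fewer samples and a fold threshold keeps fewer genes by construction, while for the other settings the cause was not tested. Of 5100 values of named genes that were called, over all settings, 4743 kept their direction and side of the threshold, 355 kept only the direction and 2 changed direction. Of 780 values of those not called, 752 stayed so and 28 passed. Signal over background limits genes that were dim in a group, for which only a bound is given.

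The labels do not say whether the replicate numbers pair the arrays. Arrays with the same number had correlations of their deviations from the group means of -0.20 to 0.22. For arrays with different numbers the correlations were -0.23 to 0.20. Deviations within a group depend on each other, and so few arrays cannot exclude a pairing. With the replicate number as a block, 5763, 0 and 4647 genes were called in the 3 comparisons, with 4212 shared calls and 19, 6 and 20 lists.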

Other observations

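Striated muscle genes moved apart within their list. Of 9 skeletal muscle markers measured, 4 fell with CaCl2 against sham, 1 rose and 4 did not pass, and 6 passed when adjusted over the list alone (camera adjusted p = 0.266). Tnnc2, fast troponin C, had a log2 change of -2.98 ± 0.30 (SE, limma adjusted p = 0.000599), Acta1, skeletal actin, one of -2.48 ± 0.31 and Myoz1, a Z-disc gene, one of -1.82 ± 0.17, whereas Tnni2, fast troponin I, rose by 1.92 ± 0.15. The median of the list was -0.42 and turned to between 0.04 and 0.15 under 4 other scalings. With CaCl2 plus IgG against sham the counts were also 4 fallen and 1 risen (camera adjusted p = 0.290), and the median of -0.20 turned to between 0.00 and 0.04 under the same 4 scalings. Tnnc2 had a change of -2.82 and Tnni2 one of 1.92 there.

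Among markers of nerve and Schwann cells, 3 of 9 rose with CaCl2, 1 fell and 5 did not pass, and 4 passed when adjusted over the list alone (camera adjusted p = 0.203). The myelin gene Mbp rose by 1.87 ± 0.16 (SE, log2) and S100b by 0.80 ± 0.19. Th, tyrosine hydroxylase of sympathetic nerves, had a log2 change of -0.95 ± 0.27. With CaCl2 plus IgG against sham 3 rose and 2 fell (camera adjusted p = 0.165), with Mbp at 1.75 and Th at -0.91. Of 3 mesothelial markers 1 rose with CaCl2 (camera adjusted p = 0.810), and of 3 adrenal and kidney markers 2 rose (camera adjusted p = 0.185). The 4 erythroid genes measured did not pass in any comparison as genes (camera adjusted p = 0.872 for CaCl2 against sham and 0.454 for CaCl2 plus IgG against sham). Medians and tests differed in sign for erythroid genes, with a median of 0.21 and a test that pointed to lower, and for mesothelial markers, with a median of -0.04 and a test that pointed to higher, in CaCl2 against sham. In CaCl2 plus IgG against sham, mesothelial markers had a camera adjusted p of 0.667, adrenal and kidney markers 0.0737, endothelial markers 0.745 and elastic fibre genes 0.308. The medians of endothelial and mesothelial markers were -0.05 and -0.08 there, while the tests pointed to higher.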
